A study of Solanum tuberosum with 4 samples.

How the data were processed

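Leaf RNA of potato (Solanum tuberosum, cultivar Desirée) was compared between cold-treated and control plants on 4 two-colour cDNA arrays. Per the labels' protocols, plantlets multiplied in vitro were acclimatised in pots for 2 months at 21 °C by day and 18 °C by night, with 12 hours of light at 40 μmol per square metre per second. The temperature was then lowered to 4 °C for the treated plants, while controls were kept at 20 °C, and the first and second leaves were taken after 3 days. Per the labels' protocols, total RNA came from 100 mg of leaf tissue, samples with an RNA integrity number under 7 were excluded, and 15 μg of RNA per sample was reverse transcribed with aminoallyl labelling and coupled to a cyanine dye.

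Per the labels, every array carried cold-treated RNA in Cy5 and control RNA in Cy3, and 0 arrays had the dyes exchanged. The labels give 4 independent biological replicates per condition, drawn from 2 sets of plants, without saying which replicate came from which set.

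The authors' deposited value table holds 1 log ratio per clone and array for 11507 clones, taken here as log2. No header or label states the base, the direction, the centring or the normalization, and these, with the scanner, the background correction and the spot filter, are not given in the sources used here. The values run from -8.27 to 8.89. A log10 ratio of 2 intensities of 16 bits could not exceed 4.82, so base 10 was ruled out for intensities on that scale, while a natural log, which could reach 11.1, was not. Array medians were 0.003, 0.025, 0.104 and -0.020 for replicates 1 to 4. The direction was taken as likely cold over control, because the labels list the cold RNA as the first channel and as Cy5. The titles name the control first, so the opposite direction remains open, and signs are therefore reported as positive and negative.

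A second deposited table gives a p-value per clone from a one-sample t-test, per the file header. Its p-values were recomputed from the deposited log ratios with a median difference of 9.8e-05 and a largest difference of 0.0208. The 91 clones with fewer than 2 values are listed there at a p of 1.

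Depth has no meaning for an array, and no spot intensities were used, so the number of arrays limits the precision. Empty cells were left as missing. Clones with values on at least 3 of the 4 arrays were tested, which kept 10778 clones and left out 729. Each array was treated as 1 paired replicate, and the mean log ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept-only lmFit and eBayes, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold). No further normalization was applied. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

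The procedure was tested on simulated data with the same 10778 clones and missing values. Errors were independent and of the same scale on every array, and 200 clones were changed. It recovered 19.4% of 67 clones changed by 1 on the log2 scale, 71.6% of 67 changed by 2 and 97.0% of 66 changed by 4, with 8 false calls among 133. The Benjamini-Hochberg cutoff on the unadjusted p is stricter when fewer clones are called, and 1602 were called in the real data. These shares are therefore not the sensitivity of the real comparison, where the smallest change called was 0.474.

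The test, the threshold, the rule for named clones and most alternatives were fixed before the data were examined; the alternatives added later are named with their results. The rule allowed 2 positive and 2 negative clones where probes carry no gene name: those with the most extreme means among clones past the threshold with the same sign on every array. Of the clone identifiers, 0 matched the RefSeq gene table of assembly SolTub_3.0, which holds 32873 genes. Gene names, positions in the genome and pathway lists were therefore not analysed here. The alternatives covered centring, normalization between arrays, the number of values needed, the variance model, array weights, a fold threshold, the plain t-test and leaving out each array.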

Results

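The series measured transcript levels in leaves of potato plants of the cultivar Desirée after 3 days at 4 °C, against control plants kept at 20 °C. Each of the 4 arrays hybridised RNA from cold-treated leaves together with RNA from control leaves, so that each array gave 1 ratio per spotted cDNA clone and served as 1 replicate. The clones are identified only by their array names (STM followed by 2 letters and a number), and their genes were not analysed here. A positive log ratio likely means a higher level in the cold, since the labels give the cold RNA as the first channel in Cy5, but no source used here states the direction.

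The 4 arrays did not give equally complete data. Replicates 1, 2 and 4 held values for 11154, 11083 and 11293 of the 11507 clones. Replicate 3 held values for 5375 clones and lacked them for 53.3%. The spread of log ratios also differed between arrays. Over the 5210 clones measured on all 4, the SD across clones was 0.865 on replicate 1, 1.12 on replicate 2, 1.71 on replicate 3 and 0.967 on replicate 4. The tails were uneven as well. On replicate 4 the 1st percentile of these clones lay at -3.53 and the 99th at 1.44, whereas on replicate 1 they lay at -1.79 and 2.85.

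**Figure D1:**
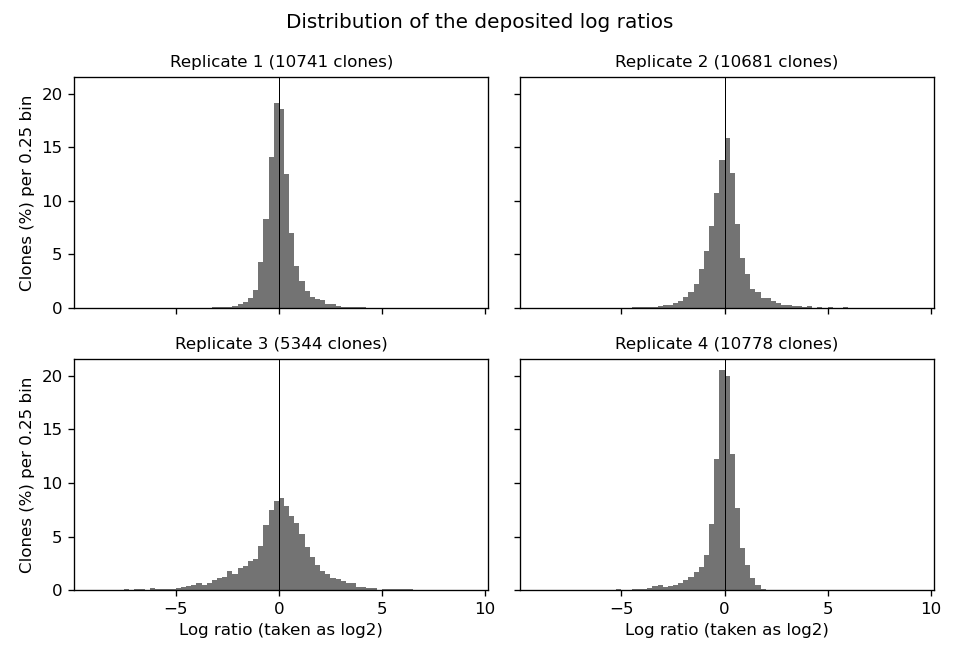
Percent of clones per bin of 0.25 of the log ratio (taken as log2) on each array, for the tested clones with a value on that array. Replicate 3 has the widest distribution, and the upper tail of replicate 4 ends at 2.36.

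The first question was whether the replicates gave the same ratios. Across clones, which are not independent replicates, the log ratios of every pair of arrays were positively correlated. Replicates 3 and 4 had the highest correlation, with a Pearson r of 0.920 and a Spearman rho of 0.935 over 5375 clones. The other pairs had a Pearson r between 0.492 (replicates 1 and 4) and 0.732 (replicates 1 and 2). Of the 5210 clones with 4 values, 2972 (57.0%) had one sign on all 4 arrays, 1547 of them positive and 1425 negative. Independent signs would give 12.5%. All of these clones had a value on replicate 3, whose missing values fell more often on clones with small ratios. It lacked a value for 66.1% of clones with a mean absolute log ratio under 0.25 on the other arrays. For those at 1 or more it was 28.1%. The share of 57.0% may therefore not hold for all clones.

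The sizes of the ratios differed between the arrays. Among the 5210 clones with 4 values, clones were selected on replicate 2 to compare the other 3. The 751 clones above 1 on replicate 2 had median log ratios of 1.20 on replicate 1, 1.88 on replicate 3 and 0.745 on replicate 4. The 710 clones below -1 on replicate 2 had medians of -0.733 on replicate 1, -1.74 on replicate 3 and -1.16 on replicate 4. Replicate 3 had the largest medians in both directions. Replicate 4 was below replicate 1 in size among the first clones and above it among the second.

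The main comparison, cold against control leaves, called 1602 of 10778 clones (14.9%) at an adjusted p under 0.05 (limma, Benjamini-Hochberg). Of these, 886 had a positive and 716 a negative mean log ratio. With replicates 3 and 4, the pair with the highest correlation, averaged and counted as 1 (a setting chosen after seeing the data), 827 positive and 438 negative clones were called. All 1602 had the same sign on every array that measured them. This follows from the threshold, which a clone with 3 or 4 values of mixed signs could hardly reach. It is no separate evidence that the replicates agree. Taken as log2, the median of the positive calls was 1.29 and that of the negative calls -1.20, and the smallest change called was 0.474. At least a doubling (an absolute mean of 1 or more) was found for 624 positive and 446 negative clones, a mean of 2 or more for 166 and 131, and a mean of 4 or more for 11 and 9. Calls were made for 1221 of the 5210 clones with 4 values (23.4%) and for 381 of the 5568 clones with 3 values (6.84%). These groups differ in more than the number of values. Clones with 3 values mostly lacked replicate 3, whose missing values fell more often on clones with small ratios.

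The number of calls depended on single arrays. Each array was left out in turn with the same 10778 clones. Clones with values on all 3 remaining arrays numbered 5247, 5307, 10644 and 5210 without replicates 1, 2, 3 and 4. The other clones then had 2 values. Without replicate 1, 180 clones were called, 4 of them positive, and 505 with 154 positive among clones with values on all 3 remaining arrays. Without replicate 2 the test called 0 in either set of clones, although 2812 of the 10778 had an unadjusted p under 0.05, where the fit of all 4 arrays gave 3977. Without replicate 4 it called 443, of which 343 were positive. Without replicate 3, the array with the most missing values, it called 1127, of which 1046 were also called with all 4 arrays.

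**Figure D2:**
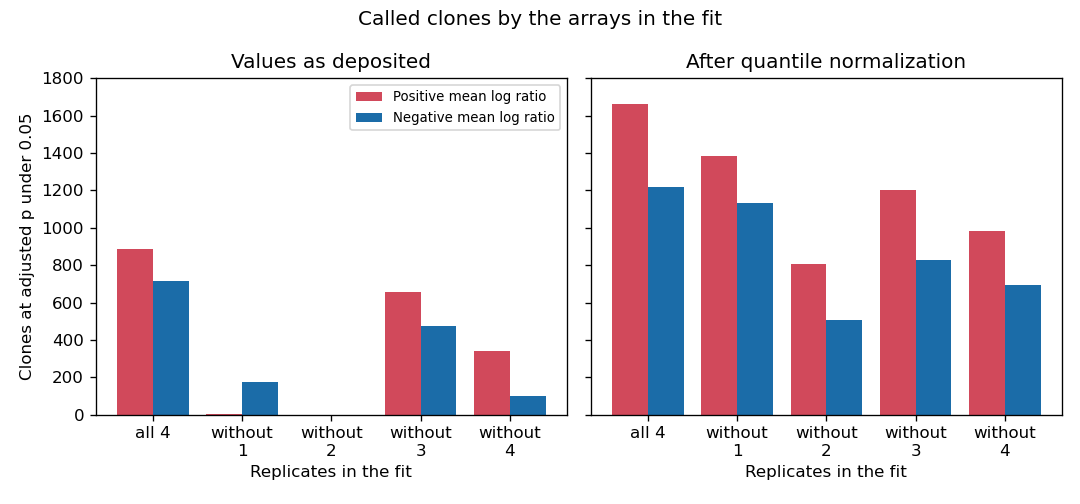
Number of clones at an adjusted p under 0.05 (limma) with a positive or a negative mean log ratio, with all 4 arrays and with each array left out, for the deposited values and after quantile normalization between arrays. With the deposited values the total falls from 1602 to 0 without replicate 2, and with quantile normalized values from 2884 to 1313. Quantile normalization gave replicate 3, which lacked 53.3% of its values, the distribution of the other arrays.

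The clone with the highest mean was STMJO29, at 5.32 ± 2.82 (SD, n = 4; standard error 1.06; limma adjusted p = 0.0366), a 40.0-fold difference if the base is 2. Its 4 ratios were 4.11, 5.98, 8.89 and 2.30 on replicates 1 to 4. STMJD93 had a mean of 5.08 ± 2.16 (SD, n = 4; limma adjusted p = 0.0298). It lay between 5.94 and 6.49 on replicates 1 to 3 and at 1.86 on replicate 4. The clone with the lowest mean was STMDP32, at -5.04 ± 1.71 (SD, n = 4; limma adjusted p = 0.0298), with -7.26 on replicate 3 and -3.25 on replicate 1. STMGD43 had the most even values of the 4 named clones, between -5.84 and -4.31, with a mean of -4.96 ± 0.708 (SD, n = 4; standard error 0.286; limma adjusted p = 0.0298). Without replicate 2 none of these 4 clones passed the threshold, while their means, at 5.10, 4.80, -4.93 and -5.17 in the order named, stayed close to those of all 4 arrays. Their adjusted p in limma was then 0.132 for STMJO29 and 0.118 for STMJD93, STMDP32 and STMGD43. With all 4 arrays, STMJD93, STMDP32 and STMGD43 shared a limma adjusted p of 0.0298 through the Benjamini-Hochberg adjustment. Their unadjusted p in limma was 0.00122, 0.000422 and 6.66e-06 in that order. Clones that share an adjusted p pass or miss the threshold together. Without replicate 1, STMJO29 (limma adjusted p = 0.0696) and STMJD93 (0.0663) missed it too. After quantile normalization between arrays (a combination chosen after seeing the data), all 4 passed it without replicate 2, at a limma adjusted p of 0.00899 for STMJO29, STMJD93 and STMDP32 and 0.014 for STMGD43, and STMJO29 (0.0017) and STMJD93 (0.00301) passed it without replicate 1.

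**Figure D3:**
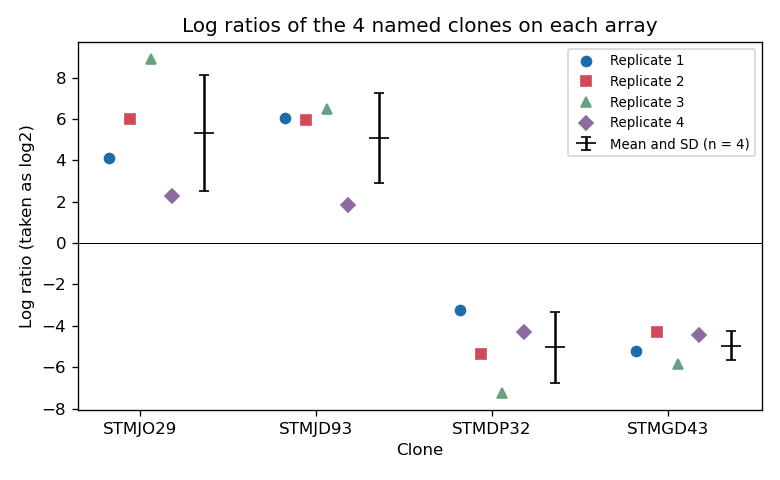
Log ratio (taken as log2) of the 4 named clones on each array, with the mean and SD over the 4 arrays as a bar beside the points. STMJO29 and STMJD93 lie above 0 on every array, with their lowest values on replicate 4 (2.30 and 1.86), and STMDP32 and STMGD43 lie below 0 on every array.

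The authors' deposited table listed 2962 clones with a p under 0.05, of which 1579 had a positive and 1383 a negative mean log ratio. Chance alone would give about 571 of the clones with at least 2 values. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 0 clones passed 0.05, and the smallest adjusted p was 0.0685, where limma, which pools the variance over clones, called 1602. Of the 1602 clones called by limma, 1534 had a p under 0.05 in the authors' deposited table and 68 did not.

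All arrays carried the cold RNA in the same dye, so dye and treatment cannot be told apart for any clone. The mean log ratio of a clone contains both.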

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

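The tests of spot position, of the likeness of replicates 3 and 4 and of the sign patterns were chosen after the result was seen. Among 10 sets of 4 values examined, 2 had an array far from the other 3, where chance marks about 1 in 20.

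Replicate 3 held 5375 clones, far below the 11083 to 11293 of the other arrays (a gap of 0.965 of the range, with a critical value of 0.829). Its missing values followed the clone number. In the odd blocks of 12 numbers (1 to 12 and every second block after it) 60.5% of clones lacked a value, against 46.1% in the even blocks, a difference of 14.5 percentage points where 1000 shuffles of the numbers within letter pairs reached at most 4.0. Such a pattern is in line with spot position on the slide. How much of the loss position accounts for stays open, since no map of clones to spots was used here. Replicate 3 holds 1.02 times as many values within 0.1 of 0 (360) as between 0.1 and 0.2 from 0 (353). This argues against a sharp cut of ratios within 0.1 of 0. A graded or wider loss of small ratios would thin both ranges, so these counts cannot decide on it. A removal of dim spots stays open too, because intensities were not used here. Clones with a mean absolute log ratio under 0.25 on the other arrays lacked a value in 66.1% of cases. Those at 1 or more did so in 28.1%, 38.0 percentage points apart. This gap cannot tell a loss of small ratios from a removal of dim spots, and no biological explanation was tested.

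Clone STMJD93 had a log ratio of 1.86 on replicate 4, with 5.94 to 6.49 on the other 3 arrays (a gap of 0.881 of the range).

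No clone was called without replicate 2, although 2812 had an unadjusted p under 0.05 in limma. After quantile normalization between arrays, leaving out replicate 2 left 1313 calls of 2884. This step gave replicate 3 the distribution of the other arrays, as if its values were missing at random. They were missing more often for clones with small ratios on the other arrays (66.1% against 28.1%, see above). Every count and p-value after quantile normalization carries this limit. A difference between the arrays in scale or shape may account for part of the calls lost without replicate 2, but this stays open. The 1313 calls lie below the 1442 (50% of the calls) set beforehand as the limit for scale, which was thus missed. They miss it by less than the SD of 514 between the counts without each array, a spread taken into account after the count was seen. That SD includes the 1313 itself and is not its error. Quantile normalization equalizes shape as well as scale (skewness 1.11 on replicate 1 and -1.82 on replicate 4 as deposited), so the count cannot tell them apart. Replicates 3 and 4 had an r of 0.939 after quantile normalization, with 0.731 for the next pair, which restates their rank agreement on the deposited values and adds no evidence on its cause. Shared plants, RNA or handling of replicates 3 and 4 is untested and open, since 2 sets of plants were sampled and the labels do not say which replicates came from which. The same is open for replicates 1 and 2, with an r of 0.732 on the deposited values. The limma p-values treat the 4 arrays as independent and would be too small if arrays shared plants or RNA.

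Of the 8 sign patterns of the 4 arrays (a pattern and its opposite taken as the same), 1, the real one, called as many as 1602 clones. The highest of the others called 0, with at most 1113 at an unadjusted p under 0.05 in limma. With 8 patterns a share under 0.05 is out of reach.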

How the results depend on the processing

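Alternatives that count replicates 3 and 4 as 1, combine a left-out array with quantile normalization, or require values on all 3 remaining arrays were chosen after seeing the data. The count of 1602 calls stayed within 1.5 times under centring on array medians, a requirement of 4 or of 2 values, robust eBayes, array weights and a 1.5-fold minimum, with 1358 (all 4 values) to 1819 calls (array weights). Quantile normalization raised it to 2884 (1664 positive, 1220 negative) and scale normalization to 2587 (1493 and 1094), of which 1587 and 1586 were among the 1602; the cause was not tested. The plain t-test called 2911 clones (1559 and 1352) at an unadjusted p under 0.05 and 0 after Benjamini-Hochberg adjustment, and the authors' deposited table listed 2962 (1579 and 1383). Leaving out 1 array gave 0 (without replicate 2) to 1127 calls (without replicate 3), with 0 to 655 positive and 0 to 472 negative. With values on all 3 remaining arrays, 505 of 5247 clones were called without replicate 1 (154 positive, 351 negative). Without replicate 2 it was 0 of 5307 (1794 at an unadjusted p under 0.05 in limma). Without replicate 3 it was 1146 of 10644 (663 and 483), and without replicate 4 it was 389 of 5210 (293 and 96). These counts rest on unlike numbers of clones, so they do not rank the arrays by influence. With quantile normalization and all 10778 clones, leaving out 1 array gave 1313 to 2518 calls (807 to 1387 positive, 506 to 1131 negative). The split between directions moved: 55.3% of calls were positive with all arrays, 2.22% without replicate 1, 77.4% without replicate 4, and 65.4% with replicates 3 and 4 counted as 1. After quantile normalization it was 57.7% with all arrays and 55.1%, 61.5%, 59.3% and 58.6% without replicates 1, 2, 3 and 4. Counting replicates 3 and 4 as 1 called 1265 clones, 438 of them negative, and shared 1198 with the 1602. The causes of the left-out counts are weighed above only for replicate 2 and were otherwise not tested. Turning every sign, since the direction is not stated, makes 716 calls positive and 886 negative. The median correlation between arrays, 0.691, was 0.923 among called and 0.478 among other clones, a difference that follows from how called clones are chosen. All 22 alternatives kept the sign of the 4 named clones, as choosing extreme means of one sign all but ensures. STMJO29 and STMJD93 missed the threshold under 5 and STMDP32 and STMGD43 under 3 (adjusted p 0.000678 to 0.168, limma and plain t-test). Passes include the plain t-test at an unadjusted p. The test of within-array ratios is paired, so no block by replicate number was fitted. Averaging rows per gene and the gene lists were not run, as the clones carry no gene names here. The 19.4% recovered at a change of 1 in simulation (200 clones changed) is not the sensitivity here.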

Other observations

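The test of an offset between naming blocks was set before its result was seen, but the pattern itself was noticed in the data. Clones whose names begin with STMC were mostly lower and those with STMH mostly higher. Of 1623 tested STMC clones, 274 (16.9%) were called negative and 78 (4.81%) positive (limma, adjusted p under 0.05). Of 1429 STMH clones 37 (2.59%) were called negative and 162 (11.3%) positive. Among all 10778 tested clones, 716 were called negative and 886 positive. STMH was not alone: 9.81% of STMI and 9.69% of STMJ clones were called positive. The small blocks STMF (106 tested clones) and STMB (34) had higher shares called positive than STMH, 13.2% and 11.8%. They also had 10.4% and 14.7% called negative. Medians of the clone means were 0.107 for STMH, 0.136 for STMI and 0.098 for STMJ. Mean log ratios of the STMC clones were -0.179, -0.532, -0.659 and -0.516 on replicates 1 to 4, and those of the STMH clones 0.208, 0.248, 0.410 and 0.0396. Letter pairs accounted for 5.29% to 11.6% of the variance within an array, with at most 0.661% in 20 shuffles per array, while clone numbers accounted for none.

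A single offset for all spots of a block is argued against as the whole cause. The gap between STMH and STMC was wider at the 10th percentile than at the median on each of the 4 arrays, by 0.646 ± 0.374 (SD, n = 4). At the 90th percentile the gap was narrower than at the median on replicates 1, 2 and 4 and wider on replicate 3 (0.942 against 0.711). A hypothesis left open is that the blocks hold clones of different genes or source libraries. Mean log ratios of the 159 letter pairs were correlated between arrays (r from 0.444 to 0.880), which such a difference would give, but so might an effect of print position that recurs on every slide. Neither the clones' genes nor their libraries were used here.

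Missing values also followed clone numbers on replicate 2. There 19.6% of the 1896 clones numbered 1, 7, 13 and so on in steps of 6 lacked a value, against 0.551% of the other 9611. On replicate 1 the even blocks of 12 lacked 4.35% of values and the odd blocks 1.79%.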
